A study of Arabidopsis thaliana with 10 samples.

How the data were processed

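Inflorescence stems of Arabidopsis thaliana were taken at a height of 20 cm and divided into segments from the top. Segment I covered 0 to 3 cm, segment II 5 to 7 cm and segment III 10 to 12 cm, and segment IV, at 18 to 20 cm, was not analysed here. RNA-seq was given for segments I, II and III of the wild type (WT, accession Col) and for segment II of an atx1 mutant, with 1 library each. ATX1 encodes a methyltransferase that acts on lysine 4 of histone H3. The 6 remaining of the 10 samples, H3K4me3 chromatin immunoprecipitation and input, were not analysed here.

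The deposited values are FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), given by the authors per gene and library to 2 decimals, per the file headers. The tools and the build named for the series are Trimmomatic, HISAT, Bowtie2, RSEM and TAIR10, per the submitters' processing notes, which give no versions and no order for them. BWA and MACS2 2.1.0 are also named there, and which tool served which assay is not given in the sources used here. How reads that fit several near-identical genes were divided is not given in the sources used here either, so values of close paralogs are uncertain. Each library listed the same 23615 genes, of which 23238 were matched to gene names of the assembly TAIR10.1. Of the rest, 195 carried names the authors gave to additional transcribed loci, 74 were chloroplast and 108 mitochondrial. A total of 701 genes were at 0 in every library. Because a 0 in a table without counts can be a failed estimate, a gene at 0 in a library is described as listed at 0. No fold is printed for it. Where the gene was kept for comparison, its 0 still entered the counts, list medians and rankings of differences below.

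No read counts were used, because the values are FPKM, so the branch of the design for normalised values was followed. FPKM keeps steps of 1 fragment for short genes. Non-zero values under 1 FPKM in genes of 250 to 900 bp were used. Of these, 69.6% to 72.3% lay within 0.15 of a whole number of fragments. Evenly spread values would give 30%, but the step was fitted to these same values, so 30% is too low a yardstick. These steps put the depth at about 20100000 fragments in WT I, 19200000 in WT II, 19100000 in WT III and 19000000 in the library labelled atx1 II. At that depth 1 FPKM on 1 kb of effective length stands for about 19 to 20 fragments. The FPKM sums were 704606, 693193, 684868 and 696108 in the same order.

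The FPKM were compared as deposited, as differences of log2(FPKM + 1). A fold on this scale understates the difference of low genes. Genes with an FPKM of at least 1 in at least 1 of the 4 libraries were kept (18858 measured genes). A gene was called higher or lower when it differed by at least 2-fold, that is by at least 1 on the log2 scale. With 1 library per group there are no replicates, so there is no test between conditions, no p-value and no error on any difference, and every value below describes these libraries. WT II was compared with WT I, WT III with WT II and with WT I, and the library labelled atx1 II with WT II.

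Before the data were examined, 28 gene lists were fixed. With ATX1 counted in, they held 355 genes, of which 353 were listed and 332 measured. They cover secondary wall NAC regulators, secondary wall MYB and other regulators, secondary wall cellulose, xylan, lignin monomer synthesis, lignin polymerisation, xylem vessel cell death, primary wall cellulose, cell expansion, cell cycle, photosynthesis, cambium and vascular patterning, phloem markers, epidermis and cuticle, stomatal lineage, floral organ identity, shoot meristem, auxin response, flavonoid synthesis, H3K4 methylation machinery, genes earlier linked to ATX1, salicylate and jasmonate defence, touch and early stress, abscisic acid and cold, heat shock, circadian clock, senescence and reference genes. ATX1 was kept apart as the targeted gene, and the first 6 lists were also pooled. For each list the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its median lay outside the middle 95% of those medians, which describes the libraries and is no test. The 5 further lists, for glucosinolate synthesis, defence and clock genes outside the fixed list, were chosen after the data were seen and serve the closing section only.

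The genes named were chosen by a rule written before the data were examined. It takes ATX1 in every library, the 5 largest differences in each direction among genes with an FPKM of at least 10 in the higher library and a symbol, the 2 to 4 members of each described list with the largest difference, and SND1, NST1, MYB46, MYB83, CESA4, CESA7 and CESA8 in every comparison. Members that went against the rest of their list, and the further genes of the plots, were chosen after their values were seen. Lists given in a sentence by their count and median alone have no member named. The values of 1 member of the cambium and vascular patterning list are not reported here.

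The rule was tested on simulated libraries of the same depth with 200 changed genes. For the library labelled atx1 II against WT II, 0 of 17206 unchanged genes passed 2-fold by counting noise. With changed genes added, in 17187 genes, 96% of those set to a log2 difference of -1.5 and 100% of those set to 1.5, 3 or -3 were recovered. The changed genes were drawn only from genes well above the minimum of 1 FPKM, so recovery of lower genes was not tested. The simulation took the values of WT II, 1 kb of effective length for every gene and counting noise only. It thus says nothing about variation between plants. Alternatives tried were scaling to the same total, pseudocounts of 0.1 and 5, no minimum and a minimum of 5, a threshold of 4-fold, steps of 1.5-fold along the stem, and the gradient from WT II against WT I. Scaling by the median of ratios and WT III in place of WT II were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.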

Results

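Transcript levels were compared along the wild-type stem, from the young top segment (I) through segments II and III, and between WT and atx1 at segment II. The comparisons address how expression of secondary wall genes differs along the stem and in the mutant. The 4 libraries were of like depth, about 19000000 to 20100000 fragments each, and 17334 genes in WT I, 16957 in WT II, 17282 in WT III and 17411 in the library labelled atx1 II reached 1 FPKM.

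ATX1 (AT2G31650), the gene for which the mutant is named, was at 4.02 FPKM in WT I, 6.09 in WT II, 3.54 in WT III and 21.76 in the library labelled atx1 II. It was thus higher, not lower, in the library labelled as the mutant than in WT II, by 1.68 on the log2 scale. For this reason that library is called by its label throughout, and each direction drawn from it rests on a label that the level of ATX1 did not bear out. A value per gene does not show which part of a transcript was covered, so a higher level does not show the label to be wrong.

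Segment II of the wild type had far higher levels of secondary wall genes than segment I. Of the 98 measured genes in the 6 pooled secondary wall lists, 75 were higher by at least 2-fold, 5 were lower and 18 lay within 2-fold, with a median log2 difference of 2.08. The NAC factor SND1 (AT1G32770), a master switch of fibre wall thickening, was at 1.41 FPKM in WT I and 95.81 in WT II, and NST1 (AT2G46770) was at 18.77 and 44.75. Downstream, MYB46 (AT5G12870) was at 10.69 and 48.32 and MYB103 (AT1G63910) at 1.96 and 186.97, while MYB83 (AT3G08500) lay within 2-fold at 3.55 and 4.56. The secondary wall cellulose synthases CESA4 (AT5G44030), CESA7 (AT5G17420) and CESA8 (AT4G18780) were at 26.67, 23.51 and 29.5 FPKM in WT I and at 553.74, 429.85 and 328.51 in WT II.

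The separate wall lists went the same way. Among 14 NAC regulators 9 were higher and 2 lower (median 1.28); SND2 was at 5.3 and 129.55 FPKM and NST2 at 0.09 and 14.43, whereas the vessel regulators VND1 (2.01 and 0.14) and VND2 (4.07 and 0.88) were the 2 lower ones. Of 23 MYB and other regulators 19 were higher and 0 lower (median 1.84), with MYB52 at 0.53 and 29.18 and MYB63, a regulator of lignin genes, at 1.87 and 45.07. All 10 secondary wall cellulose genes were higher (median 3.83), the chitinase-like CTL2 from 29.35 to 1242.07 and the microtubule-associated MAP70-5 from 1.2 to 53.75. For xylan 17 of 24 were higher and 1 lower (median 2.12), among them IRX15 (6.08 and 321.19), IRX15-L (9.19 and 389.11), IRX8 (7.29 and 225.06) and GUX1 (10.15 and 295.88), and F8H was the lower one (19.58 and 6.34). Lignin monomer synthesis had 15 of 16 higher (median 2.63), with PAL4 at 3.07 and 168.46, OMT1 at 40.8 and 844.8 and 4CL1 at 35.93 and 516.28. Lignin polymerisation had 5 of 11 higher and 2 lower (median 0.99); the laccases LAC4 (46.12 and 1021.27) and LAC17 (34.85 and 491.49) were higher and the peroxidases PRX72 (5.53 and 0.04) and PRX66 (47.47 and 8.6) lower. In xylem vessel cell death 3 of 5 were higher (median 1.96), among them the metacaspase MC9 (9.01 and 48.67) and XCP2 (95.75 and 402.87). Each of these 7 lists stood apart from random lists.

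**Figure D1:**
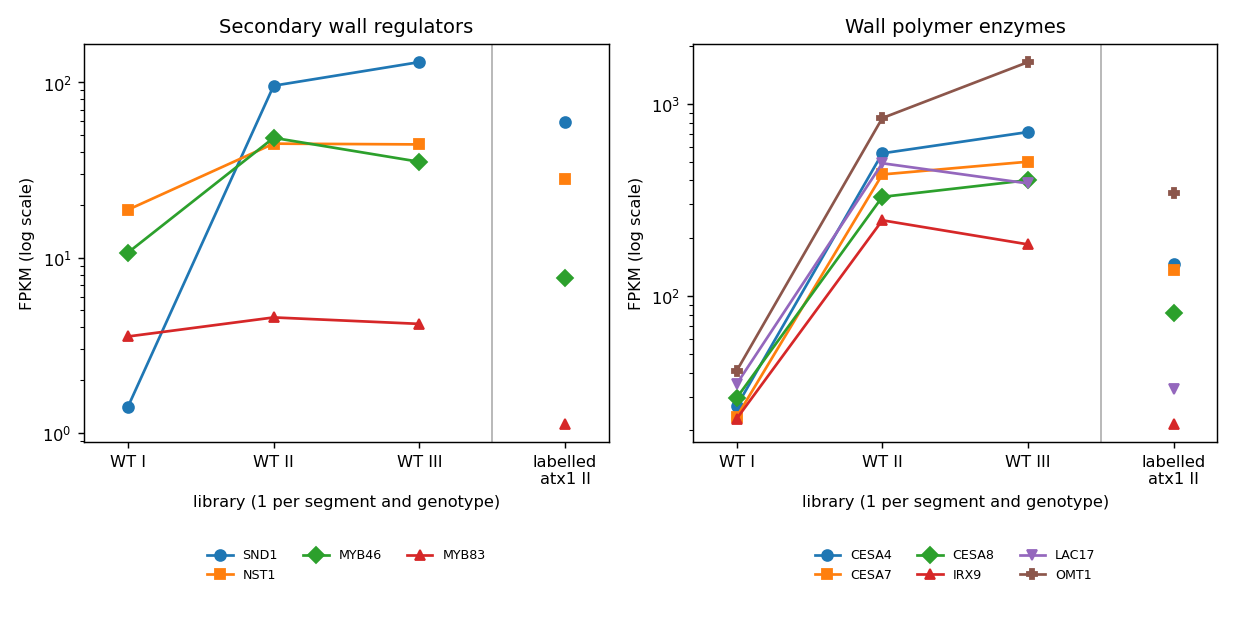
FPKM on a log axis of secondary wall regulators (left) and of enzymes of cellulose, xylan and lignin synthesis (right) in the 4 libraries, with 1 point per gene and library, and lines joining the wild-type segments only. SND1 goes from 1.41 in WT I to 95.81 in WT II. CESA4 goes from 553.74 in WT II to 147.48 in the library labelled atx1 II, whose label its ATX1 level did not bear out.

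Genes of division, growth, the cuticle and flavonoids were lower in segment II than in segment I. All 23 measured cell cycle genes were lower (median -1.78), including PCNA1 (21.91 and 2.46 FPKM), the cytokinesis syntaxin KN (33.19 and 6.04), PCNA2 (21.19 and 3.95) and CDC20.1 (26.49 and 5.14). In cell expansion 11 of 21 were lower and 2 higher (median -1.20), with the expansin EXPA5 at 84.91 and 1.29 and XTH19 at 32.07 and 2.39. In epidermis and cuticle 10 of 18 were lower and 0 higher (median -1.17), among them PDF1 (42.94 and 0.04), WSD1 (62.1 and 0.98), LTPG1 (180.93 and 14.06) and CER4 (135.02 and 13.09). Flavonoid synthesis had 7 of 9 lower (median -2.20), with chalcone synthase (CHS, listed as TT4, AT5G13930) at 91.11 and 0.27 and FLS1 at 40.55 and 0.27. Cambium and vascular patterning also stood apart (1 of 10 lower, median -0.63), with ACL5 at 58.07 and 27.61 and PHV, within 2-fold, at 25.37 and 13.97. On the higher side stood abscisic acid and cold (3 of 4 higher, 1 lower, median 1.71), with COR15A at 24.97 and 0.98 and RD29A at 11.69 and 48.17. Senescence (4 of 9 higher, median 0.70), with SAG13 at 0.34 and 9.87 and NAP at 0.62 and 5.37, and the circadian clock (2 of 11 higher, median 0.57), with RVE8 at 1.97 and 9.21 and ELF4 at 8.84 and 23.99, stood there too. The remaining lists did not stand apart, although 4 of 9 phloem markers were higher, with the sugar exporters SWEET11 at 16.43 and 213.67 and SWEET12 at 32.59 and 243.94. Auxin response did not stand apart either, with 6 of 17 lower and 1 higher (median -0.65). The others were primary wall cellulose (median -0.05), photosynthesis (0.01), stomatal lineage (-0.59), floral organ identity (-0.76), shoot meristem (0.04) and H3K4 methylation machinery (-0.20). Genes earlier linked to ATX1 (-0.54), salicylate and jasmonate defence (0.30), touch and early stress (-0.18), heat shock (-0.27) and reference genes (-0.14) were also among them.

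Over all measured genes, 1863 were higher in WT II than in WT I and 3031 lower, with a median over all genes of -0.13. The 5 largest differences on the higher side were IQD10 (3.33 and 316.87 FPKM), MYB103, IRX15, GolS2 (0.15 and 47.62) and PAL4. On the lower side they were the lipid transfer protein gene LP1 (2394.7 and 7.15), ADS4 (171.42 and 0.38), PRP2 (437.45 and 2.57), CHS and GASA4 (484.33 and 6.2). Scaling by the median of ratios, added after seeing the data, gave 2327 higher and 2482 lower and turned the near-0 medians of primary wall cellulose to 0.13 and of reference genes to 0.04.

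Segments II and III of the wild type differed far less than I and II. Of the 98 pooled secondary wall genes 3 were higher in WT III, 2 lower and 93 within 2-fold. Their median of 0.04 stood apart on the lower side of random lists, and it was -0.15 under median-of-ratios scaling. In WT II and WT III, SND1 was at 95.81 and 130.69 FPKM, NST1 at 44.75 and 44.3, MYB46 at 48.32 and 35.25, MYB83 at 4.56 and 4.19, CESA4 at 553.74 and 714.52, CESA7 at 429.85 and 500.76 and CESA8 at 328.51 and 401.36, all within 2-fold. Lignin monomer synthesis stood apart on the higher side (2 of 16 higher, median 0.61): FAH1, ferulate 5-hydroxylase, was at 35.49 and 230.48, 4CL2 at 20.5 and 43.09, and OMT1, within 2-fold, at 844.8 and 1652.31. Xylan (median -0.20) and lignin polymerisation (-0.24) stood apart on the lower side with 1 lower gene each, GXM2 (46.27 and 18.27) and PRX66 (8.6 and 0.94). Next in size, within 2-fold by the rule, were F8H (6.34 and 3.11) and LAC2 (424.7 and 230.64).

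Photosynthesis genes were lower in segment III, 9 of 23 by at least 2-fold and 0 higher (median -0.91). The Rubisco small subunit genes RBCS2B (6508.78 and 1760.72 FPKM) and RBCS1B (2668.69 and 843.55) and the antenna gene LHCB1.2 (53.43 and 15.41) were among them; as near-identical copies these can share reads, so the level of each is uncertain. Phloem markers were lower for 2 of 9 (median -0.68), SWEET11 at 213.67 and 58.73 and SWEET12 at 243.94 and 69.92. Epidermis and cuticle had 3 of 18 lower (median -0.27), with CER4 at 13.09 and 1.31 and CER1, of alkane synthesis, at 355.28 and 124.27. Cell expansion (4 of 21 lower, 1 higher, median -0.14) stood apart on the lower side by its median. So did abscisic acid and cold (0 of 4 past 2-fold, -0.40) and circadian clock (1 of 11 higher). The clock median of -0.15 and mean of 0.07 differ in sign. In these lists XTH18 was at 35.74 and 9.81 and EXPA8 at 2.45 and listed at 0. KIN1 was at 3.44 and 1.69 and RD29A at 48.17 and 79.76, and GI was at 4.72 and 12.77 and CCA1 at 2.91 and 1.62. On the higher side stood cell cycle (2 of 23, median 0.46), with PCNA2 at 3.95 and 11.05 and PCNA1 at 2.46 and 6.0. Cambium and vascular patterning (median 0.60 over 10 genes), with ACL5 at 27.61 and 53.96 and REV at 16.3 and 28.63, and heat shock (2 of 6, median 0.60), with HSFA2 at 87.87 and 207.87 and HSP90.1 at 53.39 and 127.06, stood there too. The other lists did not stand apart.

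In all, 538 genes were higher in WT III than in WT II and 444 lower, with a median over all genes of 0.19. This balance depended on scaling, since the median of ratios gave 310 higher and 748 lower. The 5 largest on the higher side were GSTF6 (2.06 and 39.54 FPKM), GSTF7 (2.37 and 30.09), EXT3 (3.05 and 28.86), FAH1 and IGMT4 (6.78 and 42.96), with GSTF6 and GSTF7 near-identical neighbours whose reads can be shared. On the lower side they were GER3 (67.05 and 0.12), LpxC3 (11.52, listed at 0 in WT III), BAS (12.85 and 0.11), LHB1B1 (748.74 and 80.66) and GASA6 (68.92 and 7.07). LpxC3 was listed at 0 in WT I too, and LHB1B1 was at 21 FPKM there, so neither fell steadily along the stem. Whether reads shared with close paralogs shaped the levels of LpxC3 and LHB1B1 was not tested.

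Between the ends of the sampled gradient, WT III had 2261 genes higher and 2330 lower than WT I. Of the pooled secondary wall genes 70 of 98 were higher and 4 lower (median 2.13), with all 16 lignin monomer genes higher, PAL4 at 3.07 and 288.48 FPKM and OMT1 at 40.8 and 1652.31. SND1, MYB46, CESA4, CESA7 and CESA8 were higher by 5.77, 1.63, 4.69, 4.36 and 3.72 on the log2 scale, NST1 was at 18.77 and 44.3 FPKM, and MYB83 lay within 2-fold at 3.55 and 4.19. Cell cycle genes were lower for 19 of 23 (median -1.40), with AUR2 at 12.17 and 2.67 and CYCB2;2 at 8.5 and 1.78. Epidermis and cuticle genes were lower for 13 of 18 (-1.47), with CER4 at 135.02 and 1.31 and WSD1 at 62.1 and 0.14. Photosynthesis was lower for 11 of 23 (-0.94), with LHCB1.2 at 126.95 and 15.41 and LHCB1.1 at 92.44 and 12.95, near-identical copies that can share reads. Auxin response also stood apart (10 of 17 lower, 1 higher, -1.04), with IAA29 at 0.18 and 6.11 and SAUR19 at 3.95 and listed at 0. GolS2 (0.15 and 126.52), IQD10 (3.33 and 341.25), PAL4, IRX15 (6.08 and 411.13) and GSTF2 (2.86 and 223.16) had the largest differences on the higher side, and GER3 (1682.09 and 0.12), LP1 (2394.7 and 2.14), PRP2 (437.45 and 0.22), DGR2 (309.07 and 0.57) and ADS4 (171.42 and 0.14) on the lower. Taken in steps, 1643 genes were higher in II than I and then within 2-fold in III, 2753 were lower and then within 2-fold, and 97 and 92 were higher or lower at both steps. Segment I held the highest value for 8325 genes, segment II for 3183 and segment III for 7289, and in 61 the highest value was shared.

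In the library labelled atx1 II, whose label its ATX1 level did not bear out, secondary wall genes were lower than in WT II. Of the 98 pooled genes 66 were lower by at least 2-fold, 6 were higher and 26 lay within 2-fold, and the median of -1.62 was below those of all 10000 random lists, of which the middle 95% ran from 0.00 to 0.36. In WT II and that library MYB46 was at 48.32 and 7.65 FPKM, MYB83 at 4.56 and 1.12, MYB103 at 186.97 and 14.68, CESA4 at 553.74 and 147.48, CESA7 at 429.85 and 136.07 and CESA8 at 328.51 and 82.07. SND1 (95.81 and 59.26) and NST1 (44.75 and 28.19) lay within 2-fold. Against WT III in place of WT II, a choice made after seeing the data, 68 pooled genes were lower and 4 higher (median -1.70). SND1, at 130.69 FPKM in WT III, was then lower by at least 2-fold, and NST1, at 44.3, was not.

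By list, NAC regulators had 6 of 14 lower (median -0.76), SND2 at 129.55 and 25.45 FPKM and the vessel regulators VND6 at 11.75 and 1.94 and VND7 at 5.88 and 1.43. The 2 higher members of that list were XND1 (14.74 and 36.95) and VNI2 (47.24 and 102.32). Both were also among the members higher in WT II than in WT I, where XND1 was at 3.47 and VNI2 at 18.79. Against WT III VNI2 lay within 2-fold. MYB and other regulators had 14 of 23 lower and 0 higher (median -1.29), including the zinc finger gene C3H14 (22.37 and 1.35) and MYB63 (45.07 and 4.9). Secondary wall cellulose had 9 of 10 lower (median -1.98), FLA12 at 959.6 and 90.87 and COBL4 at 426.51 and 58.61, with MAP70-5 higher at 53.75 and 154.12. Xylan had 20 of 24 lower and 0 higher (median -2.26), among them GXM2 (46.27 and 1.59), IRX9 (248.13 and 21.53) and the acetyltransferase gene ESK1 (181.71 and 15.77). Lignin monomer synthesis had 9 of 16 lower (median -1.33), with CCoAOMT1 at 2027.77 and 399.07 and CYP98A3 at 191.96 and 43.25, and FAH1 (35.49 and 154.7) and PAL3 (8.82 and 40.64) higher; against WT III FAH1 lay within 2-fold. Lignin polymerisation had 8 of 11 lower (median -2.86), LAC17 at 491.49 and 32.94 and PRX64 at 635.04 and 66.43, with PRX52 higher at 0.18 and 4.02. In xylem vessel cell death 4 of 5 were lower (median -1.74), XCP1 at 125.3 and 14.58 and XCP2 at 402.87 and 91.93. Each of these lists stood apart, and their medians stayed below 0 in every alternative run.

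**Figure D2:**
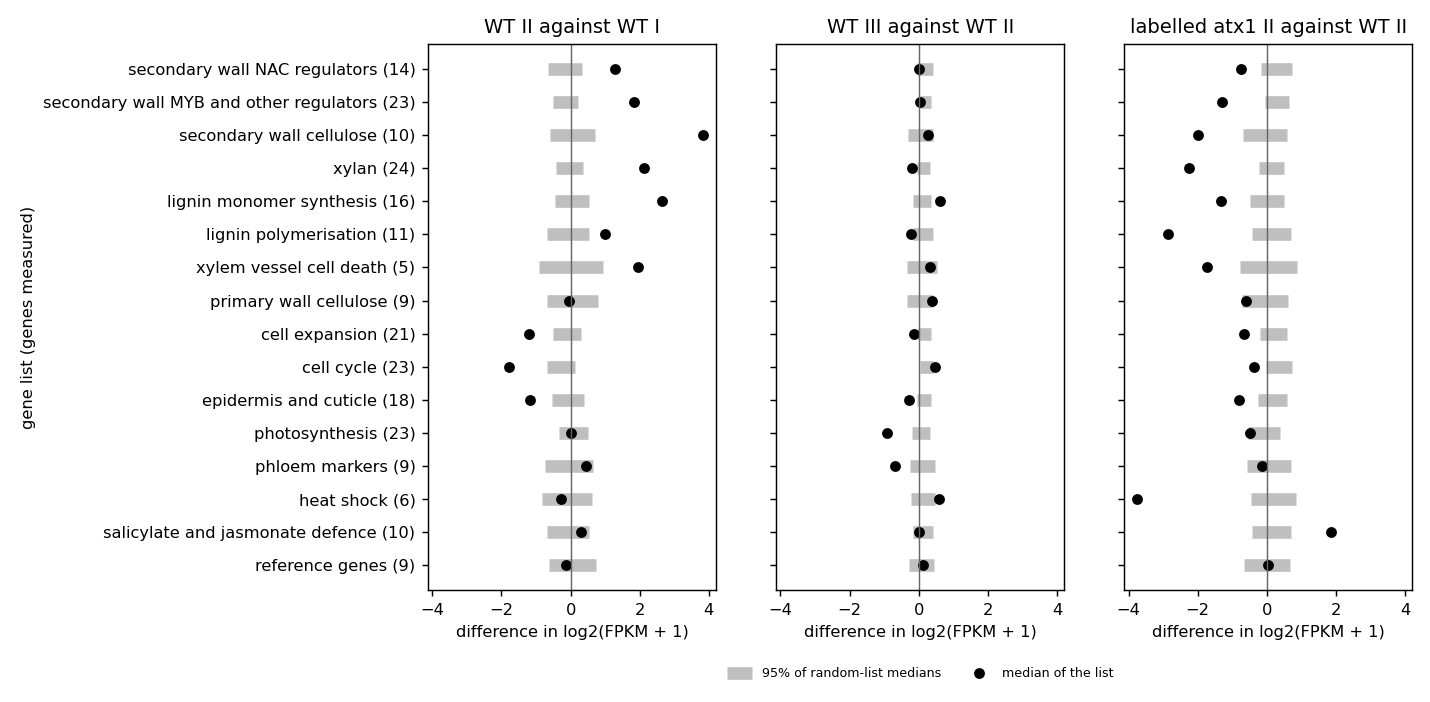
Median difference in log2(FPKM + 1) of 16 gene lists (black points, genes measured in brackets) in 3 comparisons, with the middle 95% of medians of 10000 random lists matched on expression (grey bars). The 6 secondary wall lists have medians from 0.99 to 3.83 in WT II against WT I. In the library labelled atx1 II against WT II they run from -2.86 to -0.76, a label the ATX1 level did not bear out. Reference genes lie inside the grey bar in each panel, and their near-0 medians change sign under median-of-ratios scaling.

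Other groups differed between the same libraries, again with the direction resting on the label. Heat shock genes were lower for 6 of 6 (median -3.74), HSFA2 (AT2G26150) at 87.87 FPKM in WT II and 1.37 in the library labelled atx1 II, HSP17.4 at 33.05 and 0.37 and HSP101 at 69.24 and 2.19. Salicylate and jasmonate defence genes were higher for 6 of 10 and lower for 0 (median 1.85): PR2 was at 13.25 and 114.83, VSP1 at 41.45 and 189.78, and PDF1.2 (144.11) and PR1 (3.66) were listed at 0 in all 3 wild-type libraries. In the circadian clock list, which did not stand apart by its median (0.39) but did against WT III (0.55), 5 of 11 were higher and 1 lower: the morning genes CCA1 (AT2G46830) and LHY (AT1G01060) were at 2.91 and 2.8 in WT II and at 121.08 and 108.31 in the library labelled atx1 II, PRR5 was at 5.22 and 61.91, and LUX was lower at 51.02 and 19.21. In senescence 4 of 9 were higher, SEN1 at 2.83 and 101.8 and SAG13 at 9.87 and 100.33, with a median of -0.31 and a mean of 1.12 that differ in sign, and the list did not stand apart.

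**Figure D3:**
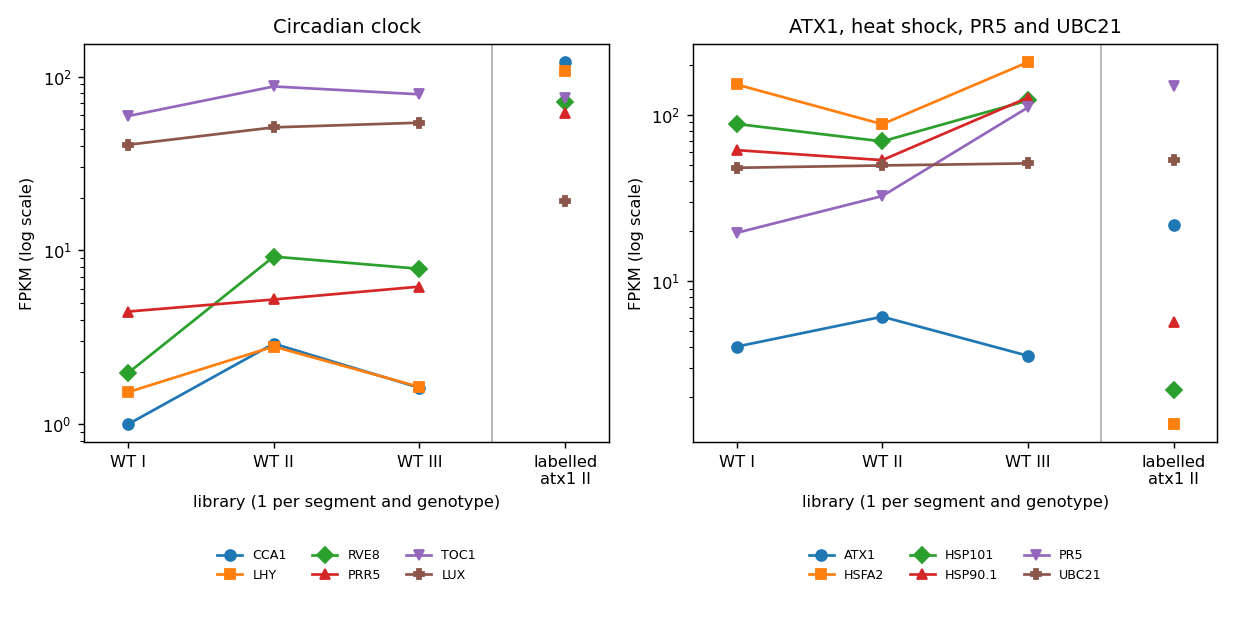
FPKM on a log axis of circadian clock genes (left) and of ATX1, 3 heat shock genes, PR5 and the reference gene UBC21 (right) in the 4 libraries, with 1 point per gene and library and lines joining the wild-type segments only. CCA1 lies at or under 2.91 in the wild type and at 121.08 in the library labelled atx1 II, HSFA2 between 87.87 and 207.87 and at 1.37, and UBC21 between 48.0 and 51.03 and at 53.17.

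Epidermis and cuticle genes were lower for 6 of 18 and higher for 0 in the library labelled atx1 II (median -0.82), CER1 at 355.28 and 5.64 FPKM and MAH1, of wax alkane oxidation, at 237.84 and 8.91. Cell expansion had 8 of 21 lower and 1 higher (median -0.67), XTH18 at 35.74 and 1.8 and EXPA15 at 39.38 and 6.64, but its median against WT III was -0.05. No cell cycle gene of 23 passed 2-fold, although the list stood apart by its median of -0.37, CDKB2;1 being at 10.84 and 5.75 and CYCB1;2 at 4.6 and 2.81. Photosynthesis genes went both ways, 3 of 23 higher and 6 lower, with LHCB1.1 at 24.95 and 815.07 and RBCS2B at 6508.78 and 782.73, paralogs whose reads can be shared. That list did not stand apart from random lists (median -0.49) and its median turned to 0.45 against WT III. Lists that did not stand apart were primary wall cellulose (2 of 9 lower, median -0.60), cambium and vascular patterning (0.25, and -0.02 under median-of-ratios scaling, with ACL5 higher at 27.61 and 129.94), phloem markers (1 of 9 higher, -0.14), stomatal lineage (-0.00), floral organ identity (-0.20), shoot meristem (1 of 5 higher, 0.35), auxin response (4 of 17 higher and 2 lower, median -0.15 and mean 0.31), flavonoid synthesis (1 of 9 higher, 0.01), touch and early stress (-0.24), abscisic acid and cold (2 of 4 lower, -0.54) and reference genes (0 of 9, 0.04). In the H3K4 methylation machinery 1 of 16 was higher, ASH2R at 2.95 and 6.92 (median 0.49). There ATX4 lay within 2-fold by the rule at 2.35 and 4.93. Of 3 measured genes earlier linked to ATX1, WRKY70 was lower at 187.06 and 87.63, NCED3 lay within 2-fold by the rule at 10.98 and 5.26, and so did XTH33 at 0.92 and 1.64 (median -0.94).

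Set against WT III in place of WT II, 6 of the 28 fixed lists changed in whether they stood apart. Cell expansion no longer did, at the median of -0.05. Primary wall cellulose then stood apart on the lower side (5 of 9 lower, median -1.02), as did cambium and vascular patterning, whose median turned to -0.44, and genes earlier linked to ATX1 (2 of 3 lower, 1 higher, median -1.66). In that last list WRKY70 and NCED3 were lower, from 278.13 and 19.53 FPKM in WT III, and XTH33 was higher, from 0.15. Photosynthesis (7 of 23 higher, 1 lower, median 0.45) and the circadian clock (5 of 11 higher, 2 lower, median 0.55) stood apart on the higher side. The cell cycle list stood apart in both settings, with 8 of 23 lower and a median of -0.74 against WT III. The medians of stomatal lineage, shoot meristem and flavonoid synthesis, which stood apart in neither setting, turned to 0.05, -0.02 and -0.06.

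Over all measured genes, 2665 were higher in the library labelled atx1 II than in WT II and 1569 lower, with a median over all genes of 0.28. Scaling by the median of ratios turned this balance to 1698 higher and 2248 lower. The 5 largest on the higher side were EARLI1 (195.33, listed at 0 in WT II), NIT2 (0.04 and 201.08 FPKM), GSTF6 (2.06 and 582.08), GRP3S (0.65 and 275.48) and PDF1.2. On the lower side they were GER3 (67.05, listed at 0 in the library labelled atx1 II), GASA6 (68.92 and 0.21), CER1, HSFA2 and RL4 (104.94 and 2.35).

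The difference between the library labelled atx1 II and WT II was then set against the wild-type gradient between WT I and WT III, which shares no library with that difference. Of the 2261 genes higher in WT III than in WT I, 366 (16.2%) were lower in the library labelled atx1 II than in WT II, where independent lists would share 188.1, and 662 (29.3%) were higher, against 319.5. Of the 2330 genes lower in WT III, 371 (15.9%) were lower in that library too, against 193.9, and 188 were higher, against 329.3. The gradient from WT I to WT II, also chosen beforehand, shares WT II with that difference, so counts for independent lists do not apply to it. Of its 1863 higher genes 425 were lower and 406 higher in the library labelled atx1 II than in WT II, and of its 3031 lower genes 243 were lower and 368 higher. In the gradient between WT I and WT III, genes higher along the stem were in excess on both sides of the comparison of the library labelled atx1 II with WT II, with secondary wall genes such as IRX15, CTL2 and PAL4 on the lower side and GSTF2 (139.13 and 1479.08 FPKM) on the higher. Against WT I, the secondary wall genes of the library labelled atx1 II were higher for 44 of 98 and lower for 17 (median 0.61), with CESA4 at 26.67 in WT I and 147.48 in that library. Across the 18858 measured genes, which are not independent replicates, Pearson's r of that library was 0.889 with WT III, 0.877 with WT II and 0.737 with WT I, and r between WT II and WT III was 0.967.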

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

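Scaling by the median of ratios and the use of WT III in place of WT II were chosen after seeing the data, and the other alternatives before. Of the counts recomputed under an alternative, 69 stayed within 1.5 times the main value and 29 did not. Of the list medians, the pooled list included, 671 stayed inside their 95% bootstrap interval over genes and 41 did not. In 1 case a list that stood apart changed sign: the pooled secondary wall lists, at 0.04 for WT III against WT II, were at -0.15 under median-of-ratios scaling. All 21 correlations of the library labelled atx1 II kept their order.

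A pseudocount of 0.1 gave 1263 higher and 796 lower genes for WT III against WT II. A pseudocount of 5 gave 1065 and 1586 for WT II against WT I, 149 and 203 for WT III against WT II, 1319 and 1372 for WT III against WT I and 1240 and 893 for the library labelled atx1 II against WT II; it left 237 gradient genes lower in that library, 978 genes higher then level along the stem and 1524 lower then level. A threshold of 4-fold gave, in the same order, 518 and 613, 31 and 50, 676 and 574, 534 and 365, then 77 gradient genes, 499 and 597, and 38 secondary wall genes lower in the library labelled atx1 II. Fewer genes pass a stricter threshold or a larger pseudocount by construction. Median-of-ratios scaling gave 310 and 748 for WT III against WT II and 1698 higher genes in the library labelled atx1 II, and steps of 1.5-fold gave 2522 genes higher then level; the cause of the scaling shifts was not tested.

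The count-based alternatives that had been planned, among them a counting interval per ratio, were not run because the values are FPKM. No alternative replaces the missing replicates, and genes under about 1 FPKM rest on few fragments.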

Other observations

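Glucosinolate and defence genes, in lists chosen after the data were seen, also differed between the libraries. Of 15 genes of aliphatic glucosinolate synthesis, 11 were higher in WT II than in WT I and 9 higher in WT III than in WT II, with 0 lower at either step; MAM1 was at 17.03, 113.7 and 562.11 FPKM along the stem and CYP79F1 at 8.27, 72.69 and 354.73. In the library labelled atx1 II 12 of them were higher than in WT II (median 1.87), but the median against WT III was 0.13. Of 6 indolic glucosinolate genes, 4 were higher in WT II than in WT I, CYP79B3 at 1.69 and 105.66, and 0 passed 2-fold between WT II and WT III. Of 8 ethylene and jasmonate defence genes, 7 were higher in the library labelled atx1 II than in WT II: PR4 was at 3.70 and 574.85, the regulator gene ORA59 at 0.11 and 45.82 and ERF1 at 0.85 and 11.72. PDF1.2 and PDF1.2c, whose reads near-identical copies can share, were at 144.11 and 82.63 there and listed at 0 in each wild-type library.

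In the weighing that follows, the tests on swapped labels, stem maturity, cell share and the harvest time of secondary wall genes were chosen after the results were seen. The test on the neighbourhood of ATX1 was chosen after ATX1 and before its neighbours had been seen, and the morning and evening lists after CCA1 and LHY had been seen and before their own values.

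ATX1 was higher in the library labelled atx1 II than in any wild-type library. If the labels of that library and WT II had been swapped and the mutation lowers ATX1, the library labelled WT II should have less ATX1 than WT I and WT III; it had 1.51 times the higher of them. This ratio lies within 2-fold and, with 1 library per segment, has no spread, so it does not settle whether such a swap took place. A change over the whole chromosome neighbourhood is argued against by the 20 measured genes on each side in the order of TAIR10.1, whose median difference relative to all genes was 0.077 (95% bootstrap interval over genes -0.20 to 0.24), while ATX1 itself was at 1.41. A swap with WT II, a single wrong label, a swap with an outside sample, and an insertion allele that yields a partial or aberrant transcript stay open, since 1 value per gene does not show which part of ATX1 was covered.

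Secondary wall genes were lower in the library labelled atx1 II. A less mature segment, nearer to segment I, should carry more cell cycle transcript, but that list lay at -0.64 relative to all genes (-0.72 to -0.54). The list did not fall steadily with age, as it lay at 0.27 relative to all genes in WT III against WT II. Its interval covers genes of 1 pair of libraries, not stems, so it weighs against such a segment without excluding it. A smaller share of wall-forming cells should raise markers of every other cell type alike. Epidermis and cuticle genes instead lay at -1.09 relative to all genes (-2.05 to -0.64). That list may itself be regulated and was also lower along the wild-type stem, with a median of -1.47 in WT III against WT I. It therefore does not decide. Photosynthesis genes, at -0.77 (-1.06 to -0.15), went both ways and were at 0.37 relative to all genes against WT III, and phloem markers were at -0.42 (-1.20 to 0.66), so neither list decides. Harvest at another time of day cannot be told apart from genotype, because the highest CCA1 level among the wild-type libraries was 2.91 FPKM and none came near the 121.08 of that library. The genotype named by the label stays open as an untested explanation. So do a smaller share of wall-forming cells, a difference in growth conditions and a segment older than III.

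CCA1 and LHY were higher in the library labelled atx1 II by 4.96 and 4.85 on the log2 scale. A candidate explanation is harvest at another time of day, for which the 13 morning genes outside the fixed clock list should be higher and the 5 evening genes not. The morning genes lay at 1.27 relative to all genes (0.39 to 2.69), LNK2 at 10.34 and 182.72 FPKM and RVE1 at 34.98 and 116.85, and the evening genes at 0.46 (-2.05 to 1.37), BOA lower at 39.81 and 10.93 and FKF1 higher at 4.56 and 16.43. Both medians met the cuts set for this hypothesis before their values were seen. The evening median did so narrowly, and it lay above that of all genes. Both intervals reach across those cuts, so the medians do not decide. Time of harvest and genotype cannot be told apart with 1 library labelled atx1.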
